A study of Mus musculus with 4 samples.

How the data were processed

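Spleen B cells from 2 Aff3+/- and 2 Aff3-/- samples were profiled on 1-colour Agilent whole mouse genome arrays. The groups and replicate numbers were taken from the labels. Per the labels' protocols, CD43-negative B cells were cultured before RNA extraction, and Cy3-labelled cRNA was made from total RNA with a low-input amplification kit.

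Per the file headers and the submitters' processing notes, the spots were read with Agilent Feature Extraction 10.7.1.1, which subtracts background and removes spatial trends, and the deposited scanner files hold 1 array each. Their processed signal and median signal are intensity values on a linear scale, per the file headers, with no normalization between arrays. Flags in the same files mark saturated, outlying and well-above-background spots. A second deposited table holds log2 values for 25372 probes. Its scale was found by setting each column against the same array's scanner values, and after centring each probe the correlation across probes was 0.9998 to 0.9999. Each of its rows is centred on the median over the 4 arrays, its direction is that of the scanner values, and its per-array scaling and its choice of probes stay unknown. Its column medians were 0.13 for Aff3+/- replicate 1, -0.04 for Aff3-/- replicate 1, -0.03 for Aff3+/- replicate 2 and 0.02 for Aff3-/- replicate 2.

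Each array held 44397 spots, of which 1377 were controls and were left out, as were spots with an outlier flag. The processed signal was put on the log2 scale, and each array's 75th percentile was subtracted (1274, 1317, 1351 and 1288 intensity units for Aff3+/- replicate 1, Aff3-/- replicate 1, Aff3+/- replicate 2 and Aff3-/- replicate 2). Spots of a probe were averaged, and 17 of 39429 probes lacked a value on some array. Probes were kept when well above background on both arrays of at least 1 genotype, which left 25136 probes and 20651 features. Each gene was represented by its probe of highest mean signal. The files pair probes with accessions only. Symbols came from a RefSeq gene table of the GRCm38.p6 assembly, used for names and for which genes neighbour Aff3, since the array design cites another build. By transcript accession 26581 probes were named, by a unique synonym 6, and 12842 kept the accession or probe ID, so that 6850 of the tested features carry no symbol. A gene whose probe found no accession in that table was not analysed here, which took in Aff3 and the immunoglobulin constant region genes.

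The Aff3-/- minus Aff3+/- difference was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 2 residual degrees of freedom per gene), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values after ± are standard errors of a log2 difference unless named as SD. The fit had no term for the replicate number, so a shift between the numbers enters these errors. A count by an unadjusted p under 0.01, a log2 difference of at least 1 and no overlap was given beside it. For a probe not well above background in a genotype, the fold is not exact. The brighter genotype's mean is set against the dimmer one's. In the dimmer genotype, each array takes the higher of the probe's own signal and the lowest signal among probes well above background. For the genes so named below, except Pf4, this equals the fitted fold. It makes no allowance for sampling error. Of 29 gene lists 28 held at least 3 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry, which asks whether a list's genes move one way on balance.

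Genes named in the text followed a rule fixed before the data were examined: Aff3, immunoglobulin constant region genes, Prdm1, Irf4, Bach2, Bcl6 and Xbp1, then the 10 highest and 10 lowest past the adjusted threshold without overlap. Where fewer passed, the places went to the smallest unadjusted p among genes with a 2-fold difference and no overlap. Each list added its members past the threshold or otherwise its 2 of smallest p. Further list members, such as Egr1, Pax5, Isg15 and Cd3e, were added as examples after their values were seen. Some genes that the rule or the lists hold are not reported here. The lists, the test and all alternatives but one were also fixed before the data were examined. Alternatives covered background correction, normalization, the deposited values, the filter, the probe rule, the variance model, the replicate number as a block and leaving out each array. A slide or scan block was not run, because 1 slide and 1 scan held all 4 arrays. No arrays were identical.

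The fit was tested on simulated data for the same comparison and 20651 features, with gene spreads drawn from the prior fitted to the arrays. Of 99 genes changed by 1 on the log2 scale, 5.05% passed the adjusted threshold and 45.5% the fold and p rule. For 100 genes changed by 2 these shares were 77% and 98%. Among unchanged genes 9 passed the adjusted threshold and 67 the fold and p rule. A list shifted by 0.3 was called at the preset correlation, the only list test run on these data, and none of the other lists was. The genes were simulated independently of each other, so this cannot show how often genes that move together give a call. The shift was also larger than the median of any list called below (at most 0.17 in size).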

Results

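The series asked how loss of Aff3, a nuclear protein of the AF4/FMR2 family whose members work with transcription elongation complexes, alters gene expression in activated mouse B cells. Splenic B cells were obtained by removing cells that carry CD43, a surface protein of T cells, plasma cells and B-1 cells that resting B-2 cells lack. They came from Aff3+/- or Aff3-/- mice and were kept for 3 days with LPS at 10 ug/mL, a bacterial TLR4 ligand, and IL-4 at 10 ng/mL, a cytokine that with LPS drives switching to IgG1 and IgE. One Cy3-labelled RNA sample was hybridised to each of 4 Agilent whole-genome arrays, with 2 arrays per genotype and all 4 arrays on 1 slide. Between 24970 and 25895 of 39429 probes were well above background on an array, and no gene spot was saturated. The small number of arrays limits the precision, and the labels do not say whether replicates came from separate mice, so the p-values measure only the spread between these samples. The Aff3 transcript itself was not analysed here, because none of the 7 Aff3 accessions in the naming table matched a probe, so a fall of its transcript in Aff3-/- cells was not shown. Of the unnamed probes, 2 that share an accession absent from that table are possible Aff3 probes, an identity these files do not settle. Both were well above background on all 4 arrays, those of Aff3-/- cells included. They differed by -0.12 and +0.03 (log2) between Aff3-/- and Aff3+/- cells. Each direction below rests on the labels alone.

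Comparison of Aff3-/- with Aff3+/- cells asked which transcripts depend on Aff3 after activation. Differences were small. Among genes above background on every array, 98.3% differed by less than 0.5 on the log2 scale. Ladinin Lad1 (log2 difference +1.18 ± 0.25, SE), the prostaglandin synthase Ptgs1 (+1.55 ± 0.37) and the translation termination factor Gspt2 (+1.05 ± 0.22) were brighter on both Aff3-/- arrays than on either Aff3+/- array. Eps8l1, an actin regulator of the Eps8 family, was dimmer on both, at -2.78 ± 0.44 (SD, n = 2) against -1.66 ± 0.17 (log2 relative to the array's 75th percentile), a difference of -1.13 ± 0.25. None of these genes passed the adjusted threshold (adjusted p = 1.00 for each). No feature of the 20651 tested did so with limma, where the smallest adjusted p was 0.74. An unadjusted p under 0.05 was reached by 422 features, fewer than the 1033 expected by chance.

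A second rule, an unadjusted p under 0.01 with at least a doubling and no overlap between the genotypes, took 17 features, 9 brighter and 8 dimmer in Aff3-/- cells. In simulated data with independent arrays 67 unchanged genes met this rule. The brighter share of 52.9% depended on the setting: it was 64.7% with quantile normalization, 100% of the 1 feature with normexp, 0% of the 9 in the deposited values, 13.4% without Aff3-/- replicate 1 and 75.7% without Aff3+/- replicate 2. Of these 17, 11 carried a gene symbol, and 10 were not well above background in one genotype, so that their folds are not exact. The folds given for them are the fitted ones and are no lower limits. The 95% interval of the log2 difference was 1.19 to 2.08 for Adam1b and -2.96 to -0.76 for Lrig1. Adam1b was 3.11-fold and Gprin3 2.93-fold brighter in Aff3-/- cells, and Tppp3 2.02-fold. Lix1 was 3.13-fold dimmer, Lrig1, a negative regulator of receptor tyrosine kinases, 3.63-fold dimmer, and Btbd35f5 2.21-fold dimmer. The smallest p belonged to the unnamed BC058677, 3.41-fold brighter in Aff3-/- cells and chosen after its values were seen. The count moved to 1 with normexp background correction and to 126 without the filter on dim probes. Without 1 array a lone array meets the no-overlap part of the rule more easily. Counts and shares from such fits therefore come from a looser rule than the 17.

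The ranked genes were filled up with genes that differed at least 2-fold without overlap but missed that p. On the brighter side these were Ccr4 (+1.01 ± 0.26, SE), the receptor for the chemokines Ccl17 and Ccl22, and the troponin Tnni1 (+1.49 ± 0.44). Pf4 (4.10-fold) and Vmn2r61 (2.10-fold) were also brighter, with folds that are not exact. The dimmer side held Xlr (-1.02 ± 0.33), an X-linked lymphocyte-regulated gene, Myh3 (2.60-fold) and Vmn1r194 (2.06-fold), the last 2 with folds that are not exact. Syna (-1.10 ± 0.46) and Syce1 (-4.67 ± 1.44), also dimmer, were each well above background on only 1 of the 2 Aff3-/- arrays. The difference of Syce1, which encodes a synaptonemal complex protein, is not exact: its Aff3-/- arrays lay at -10.02 and -5.85, the first below the lowest well-above-background signal of that array (-9.92). For Slc12a5 the 2 probes disagreed, with -1.01 for the brighter probe and +0.13 for the other. Of 61 features with a 2-fold difference and no overlap, 27 had only an accession, a predicted-gene number, a clone name or a probe ID and were left out of the ranking. Across all features 19.6% showed no overlap, where chance gives 33.3% for 2 arrays against 2 that vary independently.

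**Figure D1:**
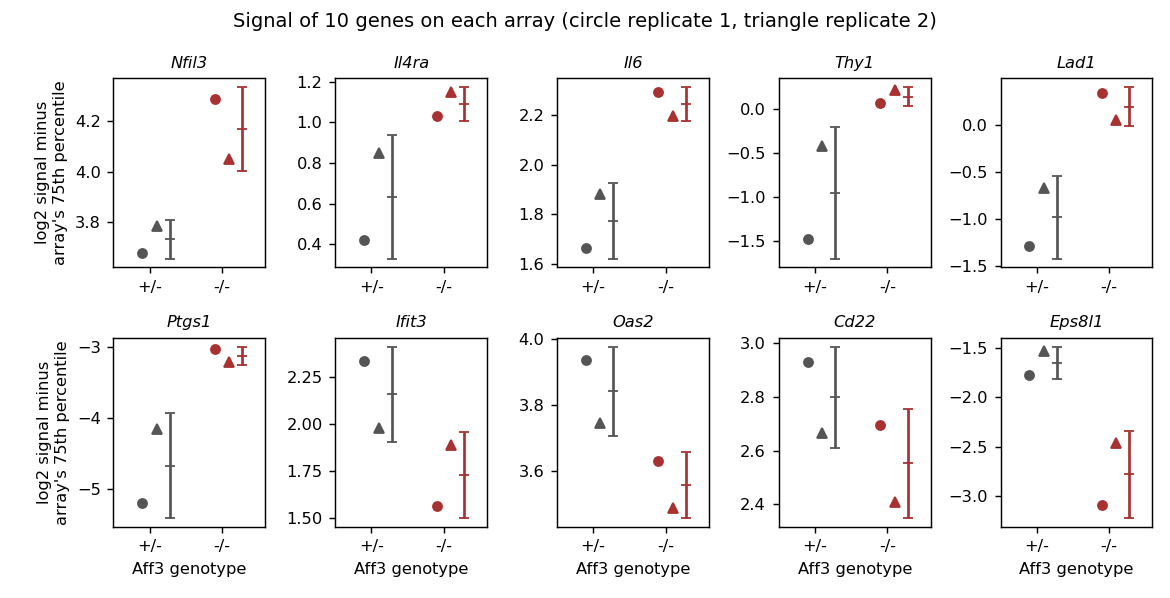
Each panel shows 1 gene, with the Aff3 genotype on the horizontal axis and the log2 signal relative to the array's 75th percentile on the vertical axis. Circles are replicate 1, triangles replicate 2, and the dash with its bar is the mean ± SD of 2 arrays. Thy1 sits at -1.48 and -0.42 in Aff3+/- cells and at 0.06 and 0.22 in Aff3-/- cells, and Cd22 is the one gene drawn whose genotypes overlap.

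Among the 28 gene lists tested, 7 passed Benjamini-Hochberg adjustment with camera at its preset correlation, 4 shifted up and 3 shifted down in Aff3-/- cells. All 7 calls were lost when the correlation between a list's genes was estimated from the arrays, and with fry. No single member of any list passed, either over all genes tested or adjusted over the list alone (0 genes in each of the lists).

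The IL-4 and STAT6 response list was shifted up in Aff3-/- cells (adjusted p = 0.0061). Of its 19 genes 14 were higher, with a median log2 difference of +0.09. In the deposited values its median was -0.08, where the median over all genes was -0.06. Nfil3, a basic leucine zipper factor induced by IL-4, was +0.43 ± 0.14 (SE). The IL-4 receptor chain Il4ra was +0.45 ± 0.18, but +0.09 for its other, dimmer probe. The amino acid oxidase Il4i1 (+0.20 ± 0.12) and the chemokine gene Ccl22 (+0.33 ± 0.22) also had both Aff3-/- arrays above both Aff3+/- arrays, as did 7 of the higher genes in all, whereas the cytokine receptor chain Il2rg was -0.12 ± 0.12. With an estimated correlation the list had an adjusted p = 0.75. It also missed the threshold without Aff3+/- replicate 1 (adjusted p = 0.15), without Aff3-/- replicate 1 (adjusted p = 0.12) and in the deposited values (adjusted p = 0.69).

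The TLR4 and NF-kB response list was likewise shifted up (adjusted p = 0.030), with 22 of 33 genes higher and a median of +0.04. In the deposited values its median was -0.06, as was the median over all genes there. The cytokine gene Il6 was +0.47 ± 0.13 (SE), the largest difference in this list, and the NF-kB subunit gene Nfkb2 +0.23 ± 0.11. Among the lower genes Nfkbiz was -0.19 ± 0.15. The adjusted p was 0.75 with an estimated correlation, 0.089 with normexp, 0.065 with quantile normalization and 0.67 in the deposited values. Without Aff3-/- replicate 1 the median turned to -0.008, and without Aff3-/- replicate 2 it was +0.10. Leaving out any 1 array ended the call, with adjusted p of 0.15 without Aff3+/- replicate 1, 0.23 without Aff3-/- replicate 1, 0.17 without Aff3+/- replicate 2 and 0.093 without Aff3-/- replicate 2.

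Immediate early genes, which are transcribed within minutes of a stimulus, shifted up as a list (adjusted p = 0.018). Of 21 genes 18 were higher, and the median was +0.15, against +0.02 in the deposited values, +0.07 without Aff3-/- replicate 1 and +0.10 without either Aff3+/- replicate 1 or Aff3-/- replicate 2. In the deposited values, where the median over all genes was -0.06, the list still passed (adjusted p = 0.047). The phosphatase gene Dusp2 was +0.32 ± 0.18 (SE) and the stress-induced Atf3 +0.20 ± 0.14, each without overlap. Egr2 (+0.59 ± 0.59) and Egr1 (+0.35 ± 0.90) varied more within a genotype than between them. Both were lower on the arrays of replicate number 2 than of number 1 (-1.24 and -1.88), a shift that enters these errors. For Egr2 the genotypes lay about equally far apart within number 1 and number 2 (SD of the 2 arrays 0.41 and 0.42). For Egr1 these SDs were 0.006 and 0.49. With an estimated correlation the adjusted p was 0.75, and it was 0.089 with normexp, 0.10 without the filter, 0.19 without Aff3+/- replicate 2 and 0.30 without Aff3-/- replicate 2.

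T cell markers formed the other list shifted up (adjusted p = 0.019, 11 of its 18 genes tested, 7 higher and 4 lower, median +0.17). In the deposited values the list's median was -0.10, where the median over all genes was -0.06. The list's median was +0.04 without Aff3+/- replicate 1, -0.002 without Aff3-/- replicate 1, +0.08 with normexp and +0.10 without the filter. The largest differences among them were those of Thy1 (+1.09 ± 0.37, SE), a surface glycoprotein that mouse B cells also make after LPS and IL-4, of Cd8a (+1.01 ± 0.43) and of the Wnt pathway factor Tcf7 (+0.53 ± 0.40), followed by Cd8b1 (+0.50 ± 0.55), above background on 1 of 2 Aff3+/- arrays, and the costimulatory receptor gene Cd28 (+0.33 ± 0.13). Of the genes of the T cell receptor complex and its signalling, Cd3e (-0.11 ± 0.15), Cd3d (+0.07 ± 0.12), Lck (-0.09 ± 0.12) and Lat (-0.07 ± 0.12) lay close to 0. The receptor's kinase gene Zap70, outside this list, was lower (-0.32 ± 0.13, and -0.43 for its other probe). The adjusted p was 0.75 with an estimated correlation, 0.12 with normexp, 0.069 without the filter, 0.67 in the deposited values, 0.12 without Aff3+/- replicate 1 and 0.19 without Aff3-/- replicate 1.

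The interferon response list was shifted down in Aff3-/- cells (adjusted p = 0.0061). Of its 32 genes 28 were lower, 12 of them without overlap, and the median was -0.08 (-0.14 without Aff3+/- replicate 2). Ifit3 (-0.43 ± 0.19, SE), Oas2 (-0.29 ± 0.13), Oas3 (-0.21 ± 0.11) and Ifitm3 (-0.22 ± 0.15), all antiviral effector genes, were among the 12. Isg15 (-0.03 ± 0.14) and the chemokine gene Cxcl10 (+0.11 ± 0.65) differed by less than their error. The adjusted p was 0.75 with an estimated correlation, 0.22 in the deposited values, 0.069 without the filter, 0.20 without Aff3+/- replicate 1 and 0.44 without Aff3-/- replicate 1.

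Mature and germinal centre B cell genes also shifted down as a list (adjusted p = 0.019), with 26 of 31 lower and a median of -0.10. The inhibitory receptor gene Cd22 was -0.25 ± 0.17 (SE), the B cell identity factor Pax5 -0.22 ± 0.17, Bach2, a repressor of plasma cell differentiation, -0.15 ± 0.12, and the sphingosine-1-phosphate receptor gene S1pr2 -0.16 ± 0.11. The germinal centre repressor Bcl6 (+0.05 ± 0.29) was not lower. The adjusted p was 0.78 with an estimated correlation, 0.052 in the deposited values and 0.12 without the filter. Without Aff3+/- replicate 1 the median turned to +0.01 (adjusted p = 0.90), and without Aff3-/- replicate 2 to +0.02 (adjusted p = 0.63), while it was -0.22 without Aff3-/- replicate 1 and -0.18 without Aff3+/- replicate 2.

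Stromal and endothelial markers were the remaining list shifted down (adjusted p = 0.030), with 6 of 12 genes tested, 5 of them lower, and a median of -0.14. The median was -0.04 without Aff3-/- replicate 2 and with normexp, -0.28 without Aff3-/- replicate 1, -0.24 without Aff3+/- replicate 2, -0.36 in the deposited values and -0.42 without the filter. Smooth muscle actin Acta2 (-0.36 ± 0.12, SE) and the endothelial cadherin Cdh5 (-0.61 ± 0.25) were lower without overlap, and Col1a2 was +0.09 ± 0.12. The adjusted p was 0.78 with an estimated correlation, 0.57 with normexp, 0.055 with quantile normalization, 0.072 with the mean of a gene's probes, 0.25 without Aff3+/- replicate 1 and 0.57 without Aff3-/- replicate 2.

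**Figure D2:**
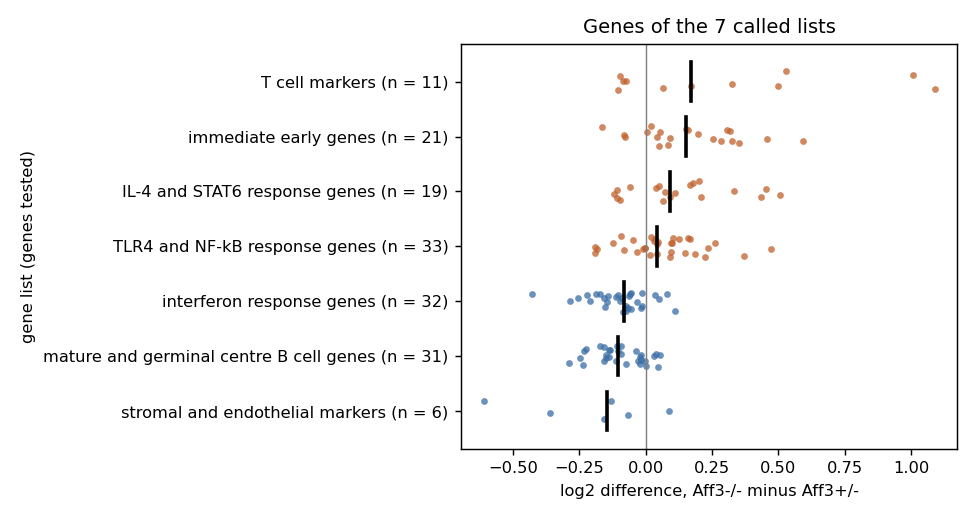
Each point is 1 gene of a list past the preset-correlation threshold, placed by its log2 difference (Aff3-/- minus Aff3+/-) on the horizontal axis, and the vertical position within a list is only for legibility. Black bars mark list medians, which run from -0.14 for stromal and endothelial markers to +0.17 for T cell markers, and most genes lie close to 0.

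Class switch recombination factors gave no shift that passed over all 4 arrays (adjusted p = 0.25, median +0.04 over 40 genes, 27 higher and 13 lower), but they passed upward without Aff3-/- replicate 1 (median +0.10, adjusted p = 0.016) and in the deposited values (adjusted p = 0.047). The end-resection gene Rbbp8 was +0.19 ± 0.12 (SE) and the splicing regulator Hnrnpl -0.19 ± 0.11. Of the immunoglobulin constant region and J chain list only Jchain could be matched to a probe, and it was +0.33 ± 0.17 with no overlap. Plasma cell differentiation genes had a median of +0.05 (adjusted p = 0.12, 14 of 21 higher). In that list Eaf2, an elongation factor partner, was +0.32 ± 0.16 (+0.11 for its other, dimmer probe), and the receptor gene Tnfrsf13b -0.26 ± 0.13 (-0.24 for its other probe). The plasma cell factors Prdm1 (+0.04 ± 0.14), Irf4 (+0.11 ± 0.13) and Xbp1 (+0.12 ± 0.13) each differed by less than their error. Marginal zone and B-1 cell genes had a median of -0.11 (adjusted p = 0.15), with the kinase Lyn at -0.29 ± 0.11 and complement receptor Cr2 at -0.53 ± 0.32. They passed downward without Aff3-/- replicate 1 (median -0.25, adjusted p = 0.0030), without Aff3+/- replicate 2 (-0.27, adjusted p = 0.010) and in the deposited values (-0.20, adjusted p = 0.047).

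AFF family and elongation complex genes, the partners and relatives of Aff3, had a median of +0.03 (adjusted p = 0.18), with Mllt1 at +0.12 ± 0.12 (SE). Unfolded protein response genes stood at +0.04 (adjusted p = 0.17, Derl1 +0.15 ± 0.11), cell cycle genes at +0.03 (adjusted p = 0.24, Tyms +0.20 ± 0.13 and Cenpf -0.20 ± 0.14) and heat shock genes at +0.06 (adjusted p = 0.58, Hspb1 -0.19 ± 0.11). Cholesterol synthesis genes were at -0.07 (adjusted p = 0.25), migration and chemokine receptor genes at -0.10 (adjusted p = 0.20), antigen presentation genes at -0.03 (adjusted p = 0.58) and glycolysis and hypoxia genes at -0.04 (adjusted p = 0.58). The integrin chain Itgb7 was -0.39 ± 0.15 and the adhesion receptor Cd44 +0.17 ± 0.11. For p53 target and apoptosis genes (adjusted p = 0.83) the median was slightly below 0 and the mean and the test above it, although the p53 target Sesn1 was -0.43 ± 0.12. Oxidative phosphorylation genes (adjusted p = 0.73) had a median and mean just below 0 while camera ranked them upward. Genes near Aff3 on chromosome 1 had a median of -0.04 (adjusted p = 0.43), among them the decoy receptor gene Il1r2 at +0.44 ± 0.13 and the kinase Zap70 at -0.32 ± 0.13.

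Several of these lists passed with the preset correlation once an array was left out, and for cell cycle and cholesterol synthesis genes the direction depended on which. Cell cycle genes passed at +0.18 without Aff3-/- replicate 1 (adjusted p = 2.8e-04), at +0.12 without Aff3+/- replicate 2 (adjusted p = 0.0030) and at -0.09 without Aff3-/- replicate 2 (adjusted p = 0.025). Cholesterol synthesis genes passed at +0.16 without Aff3-/- replicate 1 (adjusted p = 0.0073) and at -0.31 without Aff3-/- replicate 2 (adjusted p = 2.5e-07). Heat shock genes (+0.31, adjusted p = 0.0052) and unfolded protein response genes (+0.12, adjusted p = 0.033) passed without Aff3-/- replicate 1. In the deposited values AFF family and elongation complex genes (median -0.007, adjusted p = 0.028), cell cycle genes (adjusted p = 0.014) and unfolded protein response genes (median -0.01, adjusted p = 0.047) passed upward. Their medians were just below 0 but above the median over all genes there, -0.06. Migration and chemokine receptor genes passed downward (-0.17, adjusted p = 0.028). With an estimated correlation over all 4 arrays none of the 28 lists passed.

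Markers of other cell types gave no further call over all 4 arrays. Erythroid and megakaryocyte markers had a median of -0.15 and a mean of +0.11 (adjusted p = 0.25, direction down), with the haemoglobin gene Hbb-b2 at -0.66 ± 0.22 (SE). They passed downward without Aff3-/- replicate 1 (median -0.49, adjusted p = 0.020) and in the deposited values (-0.54, adjusted p = 0.0012). Dendritic cell markers had a median of -0.02 but a mean and a test direction above 0 (adjusted p = 0.14), with the transcription factors Zbtb46 at +0.52 ± 0.16 and Batf3 at +0.42 ± 0.15, and they passed upward without Aff3-/- replicate 2 (median +0.19, adjusted p = 0.011). Macrophage and monocyte markers (median -0.12, adjusted p = 0.66), NK cell markers (-0.09, adjusted p = 0.27) and mast cell and basophil markers (+0.16, adjusted p = 0.58) did not pass. Neutrophil markers (adjusted p = 0.47) had a median just below 0 and a mean of +0.04, with Camp at +0.35 ± 0.17. All 4 tested sex chromosome genes were slightly lower in Aff3-/- cells (median -0.07, adjusted p = 0.39), and the Y-linked Eif2s3y was well above background on every array.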

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

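The normexp setting was chosen after seeing the data, since the files used here hold no mean signal and the median signal took its place. No gene passed the adjusted threshold under any of the 12 alternatives to the fit (0 genes in each, the replicate block included), and no named gene crossed it. The level of Aff3 and the slide or scan block were not run. Against 17 features by the fold and p rule, normexp gave 1, the deposited values 9, no filter 126 and probes above background on all 4 arrays 7, which tests fewer genes. Leaving out 1 array, with the lone array assumed to vary like the other genotype, gave 48 to 119. Of the 17, 9 were higher (52.9%), against 64.7% with quantile normalization, 100% of the 1 with normexp, none of the 9 in the deposited values, 36.5% without the filter and 13.4% to 75.7% without 1 array. Against 7 lists, the deposited values gave 9, of which only 2 were among the 7, normexp gave 3, no filter 3, estimated correlation 0, fry 0 and leaving out 1 array 1 to 10. T cell markers turned from a median of +0.17 to -0.10 in the deposited values, where the median over all genes was -0.06. Without 1 array, mature and germinal centre B cell genes ranged from -0.22 to +0.018, cholesterol synthesis genes from -0.31 to +0.16 and cell cycle genes from -0.091 to +0.18. The cause was not tested for any of these except the smaller set of genes. Signal over background limits the dim genes, as 10 of the 17 were not well above background in one genotype.

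The genotypes share replicate numbers, but nothing in the labels ties a number to a mouse, litter or day, and 2 pairs cannot settle it. The difference of number 1 minus number 2 correlated between the genotypes with r = 0.56 across genes, which are not independent replicates, and the first principal component (61.6% of the variance) separated the numbers. With the replicate block 0 genes passed the adjusted threshold, 1457 instead of 422 had an unadjusted p under 0.05 (1033 expected by chance), 19 features met the fold and p rule (12 of them shared, 36.8% higher) and 10 lists passed, including the same 7. Unfolded protein response (+0.04, adjusted p = 0.022), migration (-0.10, adjusted p = 0.049) and marginal zone and B-1 cell genes (-0.11, adjusted p = 0.044) were added. With an estimated correlation and no block these 3 had adjusted p = 0.75, 0.75 and 0.84.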

Other observations

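Cell cycle genes were shifted up on the arrays of replicate number 2 relative to number 1 (median log2 difference +0.22 over 38 genes, camera with the preset correlation, adjusted p = 2.2e-08), with the cyclin genes Ccne2 (+1.18), Ccne1 (+0.79) and Ccnd3 (+0.70) among them. Cholesterol synthesis genes (+0.32, adjusted p = 3.1e-04; Lss +0.88) and heat shock genes (+0.35, adjusted p = 0.0098; Hsph1 +0.98) were shifted the same way, as were oxidative phosphorylation genes (+0.10, adjusted p = 0.0018) and class switch recombination factors (+0.14, adjusted p = 0.0053). Mature and germinal centre B cell genes (-0.26, adjusted p = 3.1e-04), marginal zone and B-1 cell genes (-0.33, adjusted p = 0.0035) and antigen presentation genes (-0.16, adjusted p = 0.015) were shifted down, with Bcl6 at -0.56 and Cd5 at -0.77. With an estimated correlation none of the 8 lists passed (adjusted p = 0.91 for each). No single gene passed with limma, the smallest adjusted p being 0.096, but 5977 features had an unadjusted p under 0.05 against 422 for the genotype, which points to a structure of the samples. The genes of this paragraph and the next were chosen after their values were seen.

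Unfolded protein response genes (median +0.13, adjusted p = 0.13) and immediate early genes (median -0.015, adjusted p = 0.87) did not pass by replicate number. Single genes of wide difference, none past the adjusted threshold, went both ways. Ddit3 (-1.38), Trib3 (-1.37), Chac1 (-1.25), Herpud1 (-0.51), Egr1 (-1.88) and Fosb (-1.35) were lower in number 2. Calr (+0.65), Hyou1 (+0.60), Nr4a1 (+1.46), Fosl2 (+1.48), Ptgs2 (+1.87) and the chemokine gene Cxcl1 (+2.43) were higher in number 2.

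Of the tests that follow, the one on T cells was chosen after its result was partly seen. For the difference between the replicate numbers, 2 technical explanations were tested. A difference in labelling, hybridisation or scanning should move the array's spike-in control probes as far as genes of the same brightness. The SD of the number 2 minus number 1 difference was 0.067 over 8 spike-in probes and 0.23 over such genes, a ratio of 0.29 with an upper 95% limit of 0.59. The ratio met the bound set in advance for arguing against that step, while its upper limit did not. This argues against that step as the whole source only weakly, and the spike-ins shared a shift of -0.27. Each spike-in probe averaged a median of 32 spots, which narrows its spread, and single spike-in spots had an SD of 0.077 and a ratio of 0.34, for which no limit was computed. Compression of signals on one pair of arrays predicts a trend with brightness, and Spearman's rho across probes was 0.049. Culture, mice and RNA extraction stay open and untested, as does position on the slide, where number 1 held positions 1 and 2.

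The second pattern was the 7 gene lists that passed by genotype with the preset correlation. The 4 arrays allow only 3 splits into pairs, too few for a share under 0.05; 2 of the 3 splits called at least 7 lists, with 7 for the genotype and 8, the highest other, for the replicate number. A candidate explanation is that genes of a list move together between arrays whatever the genotype. The remaining split, which mixes both, called 5 lists, fewer than the genotype but more than the bound set in advance to exclude this, so that the explanation cannot be told apart from an effect of Aff3 with these arrays. For the interferon and IL-4 response lists, brightness-matched random lists had medians of -1.1e-04 and -0.003. At most 0.01% of 10000 such lists shifted as far, which argues against brightness alone for these lists. Both were already among the 7 called, and the random lists do not hold genes that move together. The share does not mark called lists: marginal zone and B-1 cell genes, not called, had 0%, and the called stromal and endothelial markers 4.55%.

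The third pattern was the upward call of T cell markers by genotype at the preset correlation, with 7 of 11 genes higher. It was lost with an estimated correlation (adjusted p = 0.75), and the median of +0.17 was -0.002 without Aff3-/- replicate 1. In the deposited values the list's median was -0.10, where the median over all genes was -0.06. If RNA from contaminating T cells raised Thy1 (+1.09), which B cells also make, it should raise transcripts abundant in T cells about as far. Over the 4 measured of 6 such genes (Cd3d, Cd3e, Lck and Lat) the median difference was -0.085, with a largest standard error of 0.15. These 4 genes argue against T cells as the source of the Thy1 difference, and removal of CD43-positive cells would deplete T cells. Other T cell markers rose with Thy1, as given above: Cd8a about as far, and Tcf7, Cd8b1 and Cd28 less far. They were not part of this test, which was chosen after its result was partly seen, so the argument is weak. Lck says less here: it was bright in Aff3+/- cells (2.78, against -6.35 for Cd3d), so a small admixture might not move it. Of the 11 tested markers 10 were well above background on all arrays and 1 also stood in another list. The source of the Thy1 difference stays open.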
